A study of Oryctolagus cuniculus with 7 samples.

How the data were processed

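Gene expression was measured in rabbit foetal placenta with Agilent 2-colour oligonucleotide arrays on which RNA of line A and RNA of line R were hybridised together. Of the 7 arrays, 4 were of day 14 and 3 of day 24 of gestation. Each array was labelled by the submitters as a biological replicate, and the labels do not say whether an RNA sample came from 1 placenta or several. The dye of each line was taken from the labels: line A carried Cy5 on day 14 replicates 2 and 4 and on day 24 replicates 1 and 3, and Cy3 on the others.

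Per the file headers, the spot intensities were extracted with Agilent Feature Extraction, version 11.5.1.1 for day 14 and 10.10.1.1 for day 24, whereas the submitters' processing notes name version 10.10.1.1 and limma for the series. Each day lay on a slide of its own and was scanned on its own scanner model, so day, slide, scanner and software version cannot be told apart. The deposited intensities used here were the median signal and median local background of each channel, because the mean signal was held in the day 24 files alone. Spot flags for signal above background, saturation and outliers were also taken from these files. No spot outside the controls was saturated. The log10 ratios of red over green that the same files hold were made, per the file headers, by Feature Extraction from its processed signals, and were not used here beyond those signals.

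The authors also deposited log2 ratios for each array in 1 table, with scale, centring and direction not given in the sources used here. Set against the red over green ratios computed here, its columns had Pearson correlations across probes of 0.826, -0.844, 0.857 and -0.929 for day 14 replicates 1 to 4 and 0.867, 0.913 and 0.931 for day 24 replicates 1 to 3. With the dyes in the labels, the day 14 columns thus ran as line R over line A, and the day 24 columns ran as red over green with the dye-swapped replicate 2 not turned. The columns cannot tell this from a reversed label on day 24 replicate 2, whose label was kept here. The column medians were -0.00104, 0.00942, 0.00172 and -0.0160 for day 14 and 0.00246, -0.000475 and 0.00837 for day 24, so the columns were centred near 0. How the authors scaled them stays unknown. These values served only as an alternative, turned to one direction.

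Here, background was corrected with the normexp method at an offset of 50, and ratios were normalized within each array by loess with control spots at weight 0 (limma 3.58.1 in R 4.3.3). Control spots and outlier spots were then left out, and spots of 1 probe were averaged. Of 43603 probes, the 31112 well above background in either channel on at least 3 of the 7 arrays were tested. Ratios were fitted by limma (lmFit and eBayes) in 1 model of all 7 arrays with a line effect for each day, signed by dye, and 1 dye effect per probe. From it came the difference of line A from line R at day 14, at day 24, their mean, and the day 24 difference minus the day 14 difference. Positive values stand for higher signal in line A. The SE of a difference is that of this fit, with the dye effect taken out, and can be smaller than the spread between arrays. Day 24 was compared with day 14 by limma on the mean log2 intensity of both channels after quantile normalization of these means between arrays. P-values were adjusted by the Benjamini-Hochberg method over the tested probes, and a probe was called at an adjusted p under 0.05.

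Probes were named through the gene identifiers, accessions and symbols that the files give, matched to a table of RefSeq genes of the assembly mOryCun1.1. Exactly 1 symbol was found for 21257 probes, several for 211 and none for 20851, and 1284 more had a locus identifier without a symbol. The files name an older rabbit assembly than that table, so no coordinates are given. Gene names on the array can be old.

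Fixed before the data were examined were 19 gene lists: trophoblast identity, steroid hormone synthesis and inactivation, the IGF and insulin axis, imprinted genes, angiogenesis, nutrient transport, cell cycle, glycolysis, oxidative phosphorylation, fatty acid and cholesterol metabolism, extracellular matrix, endoplasmic reticulum and heat shock stress, antigen presentation and interferon response, and markers of erythroid cells, leukocytes, maternal decidua and uterine epithelium, endothelial cells, smooth muscle and fibroblasts, and yolk sac endoderm and liver. Each gene was represented by its tested probe of highest mean intensity, which gave 8191 genes. The lists held 532 different genes, 8 of them in more than 1 list. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 19 lists of a comparison, and again with an estimated correlation. A list's median was also ranked among 10000 random lists matched on intensity in 10 bins and on probe GC content in 3 bins.

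The rule for named genes was also fixed in advance. In each line comparison, it took the 10 genes per direction of largest change among called probes of 1 sign on every array, filled to 10 by the smallest unadjusted p and then given as values that did not pass. For the change of the line difference between days it took 5 per direction. For the comparison of days it took 10 per direction with no overlap between the arrays of the days. From each list it took up to 4 members of smallest p, and of probes without a symbol at most 2 per direction. Genes named from a list were drawn from these members unless said otherwise. Where a probe was not well above background on any array of 1 side, a lower bound is given as "at least", from the lowest signal among probes above background on those arrays.

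The alternatives tried were other background corrections, normalizations, filters and variance priors, a fit without the dye effect, array weights, each day alone, the authors' values, each line's channel alone, a replicate block and leaving out each array in turn. Added after seeing the data were a robust variance prior, day 14 replicate 3 with its ratio turned, and the omission of day 14 replicates 1 and 2 together.

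The methods were tested on simulated data of 31081 probes with 100 changed by 2-fold and 100 by 4-fold. At 2-fold, 66 of 100 were recovered for the line difference at day 14, 57 at day 24, 85 for the mean of both days, 27 for the change between days and 83 for day 24 against day 14. At 4-fold these were 98, 98, 100, 89 and 97, with 3 to 6 wrong calls in each. In a simulation of the mean of both days over 8191 genes, a shift of the cell cycle list by 0.5 on the log2 scale was called and 0 other lists were. The simulated probes were independent of each other, which real probes are not. Their mean estimates were 0.95 to 1.04 times the simulated size. The changes were put directly into log2 ratios, with no background step, so these estimates cannot show whether the background offset shrinks a change. In real dim spots that offset can make a true 2-fold change smaller on this scale. On day 14 replicate 1 the median Cy3 signal was 68 over a median background of 28. The numbers recovered may thus overstate the sensitivity for such spots.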

Results

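The foetal placenta of the rabbit was compared between 2 genetic lines, A and R, whose embryos were taken from donors 48 h into gestation and carried by recipient females. Line R is a rabbit line selected for growth rate and line A one selected for litter size. Its purpose, per the series title, was the effect of the embryo's and the mother's genotype on growth of the foetus. The labels used here give the line of the placenta but not that of the recipient, so the comparison is of the lines at each stage. RNA of both lines was read on the same array, on 4 arrays at day 14 and 3 arrays at day 24. The arrays measured 43603 probes, and between 50.8% and 80.4% of the spots were well above background in a channel. The number of arrays limits the precision, with a median standard error of the line difference of 0.11 on the log2 scale at day 14 and 0.13 at day 24.

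The line ratios of replicate arrays were weakly related. Across probes, which are not independent replicates, Pearson's r between day 14 arrays ran from -0.416 for replicates 3 and 4 to 0.258 for replicates 1 and 4. Between day 24 arrays it ran from -0.0549 to 0.0555. The dyes in the labels set the direction of each array, and this direction was kept. Mean intensities of the same arrays had r from 0.994 to 0.996 within day 14 and from 0.979 to 0.989 within day 24. Even between days it ran from 0.944 to 0.963. An r of intensities follows the range of signal between probes, which ratios lack, so it cannot be set against that of ratios.

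At day 14, the first question was which transcripts differed between placentas of line A and line R. No gene passed the test, and the values of smallest p are given as such. SAG, the retinal arrestin, had a log2 difference of -0.86 ± 0.10 (SE, adjusted p = 0.449), lower in line A on each of the 4 arrays as labelled. Its 5 probes lay between -0.93 and -0.84, but the others shared sequence with the named probe and are not independent of it. KCNE1, a regulatory subunit of potassium channels, had a difference of -1.70 ± 0.33 (adjusted p = 0.948), and its other probe stood at -0.59. LACTB2, a mitochondrial endoribonuclease, stood at -0.76 ± 0.10 (adjusted p = 0.518). In the other direction, MDK, the heparin-binding growth factor midkine, had a difference of 1.16 ± 0.24 (adjusted p = 0.948), with an SD of 0.86 over the 4 arrays.

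Among the other genes named at day 14, lower values in line A were found for CENPP (-0.68 ± 0.11) and SKA1 (-0.39 ± 0.08), components of the kinetochore, for CKAP2 (-0.75 ± 0.15), a protein of the mitotic spindle, and for GSDME (-0.83 ± 0.17), a pore-forming gasdermin. DDIAS, UFSP2 and PPIL1 had differences of -0.40, -0.46 and -0.74. Higher values were found for RFX5 (0.89 ± 0.20), a transcription factor of MHC class II genes, ITGA1 (0.82 ± 0.18), a collagen-binding integrin, RNASE4 (0.78 ± 0.17), a ribonuclease, and CLSTN1 (0.67 ± 0.13). FGL2, TGDS, NPC2, ZC2HC1A and NOPCHAP1 lay between 0.42 and 0.53. TGDS had 2 probes that disagreed, at 0.45 and -0.05, and the probes of RNASE4 ranged from 0.16 to 0.78 and those of UFSP2 from -0.46 to -0.08. With day 14 replicate 3 turned and the model refitted, an alternative chosen after seeing the data, MDK stood at 0.65, KCNE1 at -0.55, CENPP at -0.24, SKA1 at -0.22, DDIAS at -0.21, PPIL1 at -0.36, FGL2 at 0.18 and ZC2HC1A at 0.26. The plain means of the turned ratios were 0.26 for MDK, -0.73 for KCNE1, -0.31 for LACTB2 and -0.19 for PPIL1. With limma, 0 of 31112 probes were called at day 14, 1618 had an unadjusted p under 0.05, and 1556 would be expected by chance.

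Of the gene lists at day 14, cell cycle genes were lower in line A as a group (median -0.17 over 26 genes, camera adjusted p = 4.4548e-06), and oxidative phosphorylation genes likewise (median -0.17 over 26 genes, adjusted p = 2.5319e-09). Markers of yolk sac endoderm and liver were higher (median 0.50 over 11 genes, adjusted p = 0.00730). None of these calls held with the correlation between genes estimated from the data, adjusted p = 0.740 with an estimated correlation for each of the 3 lists. The medians on replicates 1 to 4 were -0.27, -0.14, 0.10 and -0.29 for the cell cycle list and -0.11, -0.46, 0.07 and -0.19 for the oxidative phosphorylation list. No member of the lists was called, over all probes or adjusted over the list alone. In the cell cycle list, CDC6, needed to license replication origins, had a difference of -0.25 ± 0.09 (-0.10 with replicate 3 turned), and MCM3, of the replicative helicase, -0.28 ± 0.11. In the oxidative phosphorylation list, the cytochrome c oxidase subunits COX7B and COX5B had differences of -0.32 ± 0.10 and -0.30 ± 0.10, and COX5B stood at -0.19 without replicate 2. In the yolk sac and liver list, APOB stood at 1.05 ± 0.38 and at 0.43 without replicate 1. This last list rested on 1 array: its median ratio was 2.20 on replicate 1 and between -0.18 and 0.10 on the other arrays. Its adjusted p was 0.878 with the direction turned without replicate 1, 0.0873 without replicate 4 and 0.0664 from Agilent's processed signals. The leukocyte markers had a median of 0.66 on replicate 2, and the erythroid markers medians of -0.41, 0.97, 0.70 and -0.64 on replicates 1 to 4. Without replicates 1 and 2 together, an alternative chosen after seeing the data, the oxidative phosphorylation list had an adjusted p of 0.0502. For the other 16 lists the adjusted p ran from 0.0679 to 0.786.

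At day 24, the same question was asked later in gestation. No named gene passed the test. SLC45A1, a sugar transporter, had a log2 difference of -0.97 ± 0.10 (SE, adjusted p = 0.156), lower in line A on all 3 arrays (mean -0.94 ± 0.01, SD, n = 3). ITGAE, the integrin alpha E chain, and MYLIP, a ubiquitin ligase that degrades the LDL receptor, both stood at -1.03 ± 0.13 (adjusted p = 0.464). Midkine (MDK) had a difference of 1.95 ± 0.28 (adjusted p = 0.521), with a mean ratio of 1.75 ± 0.88 (SD, n = 3). COX7B2, a subunit of cytochrome c oxidase, had the largest value among the named genes, 3.38 ± 0.58 (adjusted p = 0.522), with its 5 probes between 3.15 and 3.38.

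Other genes higher in line A at day 24 by this rule were SLC7A9 (1.03 ± 0.15), a light chain of cystine and amino acid transport, TMED7, of the early secretory pathway, with a mean ratio of 1.18 ± 0.37 (SD, n = 3), POLI (0.97 ± 0.17), a translesion DNA polymerase, FASTKD3 (0.86 ± 0.13), PFKP (0.68 ± 0.12), the platelet form of phosphofructokinase, CAMP (0.63 ± 0.11), the antimicrobial cathelicidin, and ARMC10 (0.57 ± 0.10). The 3 probes of FASTKD3 ranged from 0.08 to 0.86 and the 4 of TMED7 from 0.09 to 1.15. Line R was above background for CAMP on 1 of the 7 arrays. ZIC3, a zinc finger transcription factor, had a difference of 1.26 ± 0.19 and a mean ratio of 1.44 ± 0.95 (SD, n = 3). Its 4 probes ranged from 0.09 to 1.26 and line R was above background for it on 3 of the 7 arrays. Those lower were DNASE1L3 (-1.73 ± 0.31), a secreted DNase above background on 3 of the 7 arrays in line A and 4 in line R, AARD (-1.25 ± 0.18), KCNE1 (-1.20 ± 0.17), PRR16 (-0.84 ± 0.14), LPGAT1 (-0.74 ± 0.13), an acyltransferase, SULF1 (-0.58 ± 0.09), which trims heparan sulfate, and CYP4V2 (-0.55 ± 0.10). With limma, 0 of 31112 probes were called at day 24, and 2041 had an unadjusted p under 0.05 against 1556 expected. Leaving in only the probes above background in both channels on all arrays gave 4 called probes, all of the same unnamed transcript accession and higher in line A, and chosen here after their values were seen. Among them, probe A_04_P011381 had a difference of 1.82 (adjusted p = 0.0869 over all tested probes and 0.0486 under that filter). Its SE of 0.15, after the dye effect was fitted, was smaller than the spread of its ratios, with a mean of 1.54 ± 0.84 (SD, n = 3).

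The cell cycle list was higher in line A at day 24 (median 0.26 over 26 genes, camera adjusted p = 2.1298e-05), with adjusted p = 0.900 with an estimated correlation. NUSAP1, of the mitotic spindle, had a difference of 1.00 ± 0.31, and the checkpoint kinases BUB1 and BUB1B had 0.54 ± 0.21 and 0.68 ± 0.28, and 0.24 and 0.24 without replicate 3. None of the members was called. The median ratio of this list was 0.66 on replicate 3, 0.13 on replicate 2 and 0.01 on replicate 1, and without replicate 3 its adjusted p was 0.393. For the other 18 lists the adjusted p ran from 0.0534 to 0.982. Over all lists, 0 genes were called over all probes and 4 adjusted over the list alone: CDH1, which is E-cadherin, at -0.56 ± 0.12, the cholesterol transporter ABCA1 at -0.57 ± 0.11, the laminin chain LAMC1 at -0.64 ± 0.12 and squalene epoxidase SQLE at 0.46 ± 0.10.

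A line difference irrespective of stage was sought as the mean of the day 14 and day 24 effects, which can also arise from 1 day alone. Midkine had a mean difference of 1.55 ± 0.19 (SE, adjusted p = 0.381), higher in line A on 6 of 7 arrays as labelled, although no gene passed the test. With day 14 replicate 3 turned and the model refitted it stood at 1.33, higher on 5 of 7 arrays. RNASE4 (0.75 ± 0.12), the interferon-induced kinase EIF2AK2 (0.42 ± 0.08), AAGAB (0.42 ± 0.08), the nucleotide hydrolase NUDT15 (0.34 ± 0.06), the serotonin transporter SLC6A4 (0.47 ± 0.09) and FASTKD3 (0.54 ± 0.09) were higher in line A on all 7 arrays as labelled. KCNE1 (-0.89 ± 0.11, adjusted p = 0.385), AARD (-0.86 ± 0.12), ITGAE (-0.63 ± 0.08), SAG (-0.53 ± 0.07) and SULF1 (-0.39 ± 0.06) were lower in line A on all 7 arrays as labelled. With day 14 replicate 3 turned, 6 of 7 arrays are left in the same direction for each of these genes by arithmetic, which tests nothing. Turning that replicate moved the day 14 mean ratio of FASTKD3 from 0.22 to -0.11, of NUDT15 from 0.32 to 0.07 and of SULF1 from -0.20 to -0.02. That of KCNE1 moved from -0.59 to -0.29, of AARD from -0.46 to -0.18 and of SAG from -0.86 to -0.47. KCNE1 had a second probe, at -1.67. The mean ratios at day 14 and day 24 were -0.86 and -0.18 for SAG and -0.23 and -1.03 for ITGAE, so 1 day weighed more.

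TMED7 (0.74 ± 0.11), SLC7A9 (0.66 ± 0.10) and POLI (0.58 ± 0.11) were also among the genes of smallest p, as were PINLYP (-0.97 ± 0.17), SLC35B4 (-0.92 ± 0.16), CEP350 (-0.69 ± 0.12), LACTB2 (-0.61 ± 0.07) and SLC45A1 (-0.46 ± 0.06). The day 14 mean ratio of POLI was 0.18, and -0.22 with replicate 3 turned. SLC45A1 had mean ratios of 0.05 at day 14 and -0.94 at day 24, so its value came from day 24. The probes of FASTKD3 disagreed, from -0.15 to 0.54, those of TMED7 ranged from about 0 to 0.80, and the other probe of CEP350 stood at -0.05. With limma, 0 of 31112 probes were called for the mean of both days and 1695 had an unadjusted p under 0.05. Leaving out day 14 replicate 4 gave 1 called probe, of SERPINA9, named after its value was seen, at -2.08 (adjusted p = 0.0194), against -1.77 with all arrays (adjusted p = 0.583).

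**Figure D1:**
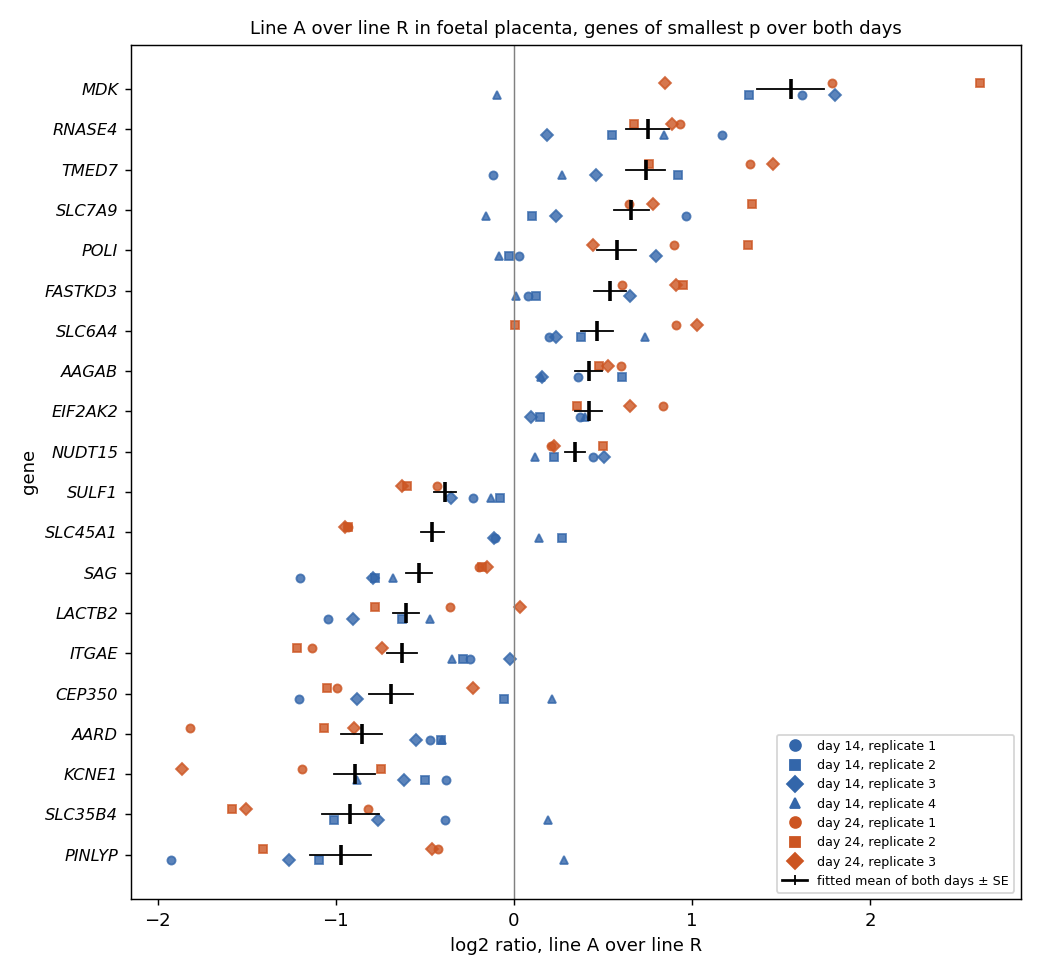
Log2 ratio of line A over line R (horizontal axis) for the 20 genes of smallest p in the mean of both days (vertical axis), with a point for each of the 4 day 14 arrays and 3 day 24 arrays and a black bar for the fitted mean ± SE. Points of KCNE1, AARD, ITGAE, SAG and SULF1 all lie below 0, and those of MDK spread from below 0 to above 2, and none of these genes passed the test.

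Over both days, erythroid cell markers were higher in line A (median 0.22 over 11 genes, camera adjusted p = 0.0331), yolk sac and liver markers were higher (median 0.31 over 11 genes, adjusted p = 0.00555) and oxidative phosphorylation genes were lower (median -0.07 over 26 genes, adjusted p = 0.00555). For each of them the call was lost, adjusted p = 0.768 with an estimated correlation. HEMGN, a nuclear protein of haematopoietic cells, had a difference of 0.75 ± 0.31, alpha globin HBA 0.84 ± 0.39, and COX5B -0.24 ± 0.08. Without day 24 replicate 2, HEMGN stood at 0.49 and COX5B at -0.16, and with day 14 replicate 3 turned HBA stood at 0.47. The erythroid median stood at -0.41 and -0.64 on day 14 replicates 1 and 4, and with day 14 replicate 3 turned the list had an adjusted p of 0.396. Each call also ended when single arrays were left out. The adjusted p of the erythroid list was 0.0696 and 0.204 without day 14 replicates 2 and 3, and 0.0578, 0.254 and 0.0870 without day 24 replicates 1, 2 and 3. That of the oxidative phosphorylation list was 0.0723 and 0.0696 without day 14 replicates 1 and 2, 0.254 without day 24 replicate 2 and 0.166 from Agilent's processed signals. That of the yolk sac list was 0.492 without day 14 replicate 1, and 0.0597 and 0.0870 without day 24 replicates 1 and 3. For the other 16 lists the adjusted p ran from 0.279 to 0.801.

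**Figure D2:**
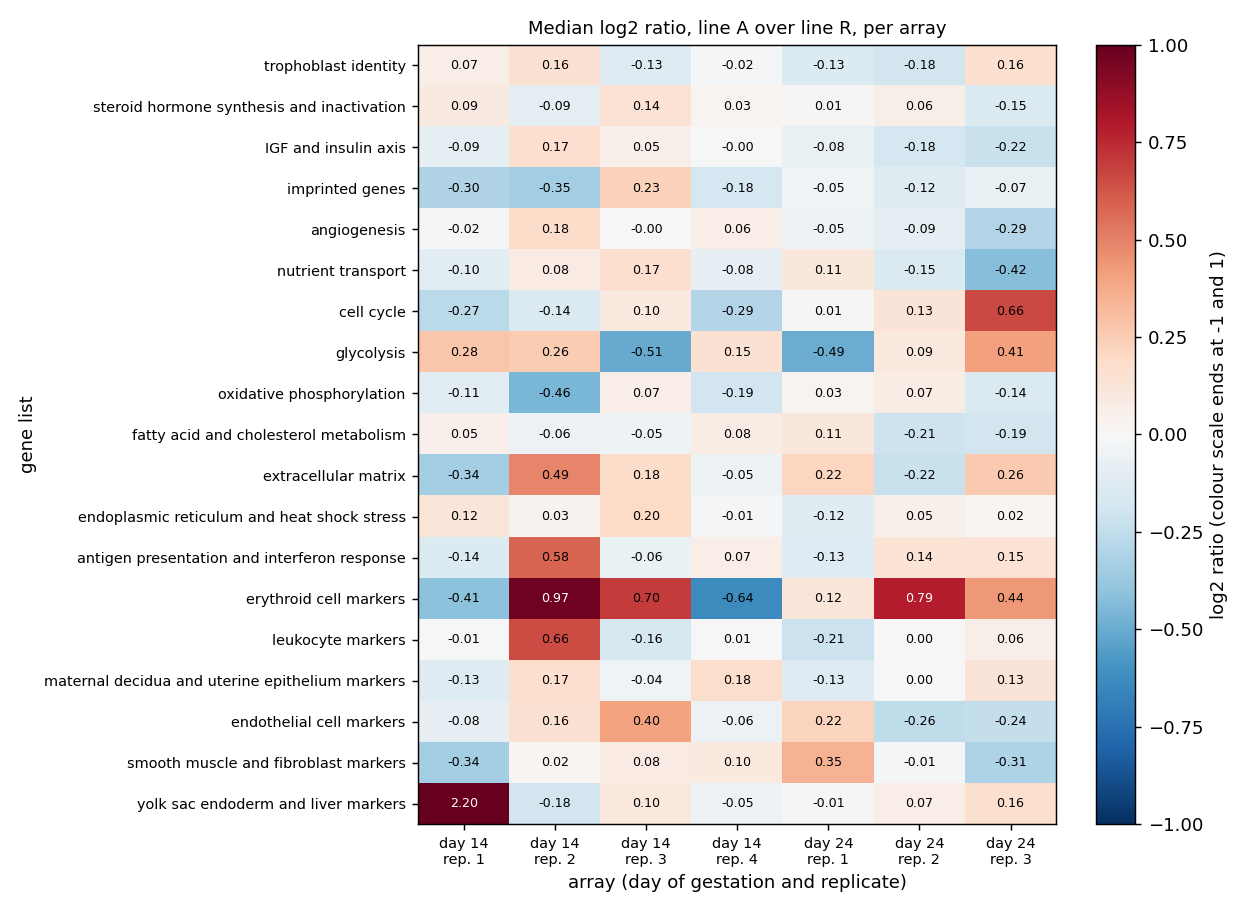
Median log2 ratio of line A over line R of each gene list (rows) on each array (columns), written in the cell and shown by colour. The yolk sac and liver markers stand at 2.20 on day 14 replicate 1, the leukocyte markers at 0.66 on day 14 replicate 2 and the cell cycle list at 0.66 on day 24 replicate 3.

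Whether the line difference changed with stage was tested as the day 24 difference minus the day 14 difference. SRD5A1, the steroid 5-alpha-reductase, had a change of -0.99 ± 0.16 (SE, adjusted p = 0.699): its ratio of line A over line R was 0.42 ± 0.20 (SD, n = 4) at day 14 and -0.59 ± 0.18 (SD, n = 3) at day 24, and its 5 probes lay between -1.03 and -0.93. With day 14 replicate 3 turned its day 14 mean was 0.06 and its refitted change -0.67, and the changes of SAG and CLEC1B, given below as labelled, were 0.55 and 0.42. SLC45A1 had a change of -1.02 ± 0.13 (adjusted p = 0.649), MYLIP -1.16 ± 0.17, PRR16 -1.05 ± 0.18 and ZC2HC1A -0.70 ± 0.12. In the other direction stood ZIC3 (1.36 ± 0.25), with its 4 probes between -0.04 and 1.36, SAG (0.88 ± 0.17), CLEC1B (0.68 ± 0.13), a platelet lectin receptor, SPAG5 (0.67 ± 0.13), of the mitotic spindle, and OGFOD1 (0.63 ± 0.12). None of these genes passed the test, and with limma 0 of 31112 probes were called while 2063 had an unadjusted p under 0.05.

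For cell cycle genes, the difference was higher at day 24 than at day 14 by a median of 0.36 over 26 genes (camera adjusted p = 4.6515e-10), with CCNB2 at 0.73 ± 0.30, CCNA2 at 0.69 ± 0.28 and MCM4 at 0.55 ± 0.17. Without day 24 replicate 3, CCNB2 stood at 0.37 and CCNA2 at 0.36. Oxidative phosphorylation genes had a median change of 0.19 over 26 genes (adjusted p = 3.3275e-05), with COX7B at 0.46 ± 0.15. Both calls were lost, adjusted p = 0.629 with an estimated correlation, and without day 14 replicates 1 and 2 together the oxidative phosphorylation list had an adjusted p of 0.176. Over all lists, 0 genes were called over all probes and 2 adjusted over the list alone, SRD5A1 and ABCA1 (-0.78 ± 0.15). For the other 17 lists the adjusted p ran from 0.155 to 0.915. Day and slide cannot be told apart in this comparison.

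The line effects of the 2 days were almost unrelated across 31112 probes, with Pearson's r of 0.0604 and Spearman's rho of -0.0621. As no probe was called at either day, the planned share of called probes of the same sign has no value. Of the 694 probes with an unadjusted p under 0.01 at either day, 382 had the same sign at both, 55.0%. The correlation changed sign with the arrays used: it was -0.0547 without day 24 replicate 2, -0.0625 without day 24 replicate 3 and 0.196 without day 24 replicate 1. It was 0.117 without day 14 replicate 3 and 0.00956 without day 14 replicate 4. With day 14 replicate 3 turned, an alternative chosen after seeing the data, it was 0.125, with 562 of 971 probes of the same sign, 57.9%.

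Between day 14 and day 24, both lines combined, transcripts of cell division were lower in the placenta. Of 26 measured cell cycle genes 25 fell and 1 rose, with a median of -2.19 (camera adjusted p = 1.2228e-12, adjusted p = 0.396 with an estimated correlation). CCNE1 and CCNB1, the cyclins E1 and B1, fell by 3.03 ± 0.21 (SE) and fell by 2.92 ± 0.18 on the log2 scale, AURKA, the Aurora A kinase, fell by 2.78 ± 0.10, and RRM2, a subunit of ribonucleotide reductase, fell by 2.76 ± 0.16. The member that rose was CCND1, cyclin D1, named after its value was seen, by 0.88 ± 0.14 (adjusted p = 0.00147). The counts were the same adjusted over the list alone. Over the same interval 8 of 16 leukocyte markers and 6 of 12 markers of maternal decidua rose, with list medians of 0.36 and 0.61 (adjusted p = 0.477 and 0.396 with an estimated correlation). Among all 31112 tested probes, 7396 were called higher and 8157 lower, 49.99% for both directions together.

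Genes that rose most at day 24 included KCNE1 (4.69 ± 0.28), HOP (4.30 ± 0.16), a homeodomain-only protein, ADAMTS17 (4.11 ± 0.10), a secreted metalloprotease, ACE (3.73 ± 0.34), the angiotensin-converting enzyme, the small heat shock protein CRYAB (3.69 ± 0.16) and the matrix glycoprotein SPARCL1 (3.63 ± 0.20). RGCC, HIGD1B, WNT3 and C18H19orf33 rose by 2.97 to 3.51. The 6 probes of ACE differed in size, from 0.81 to 3.79, and the 6 of SERPINF2 from -3.62 to -0.61. Those that fell most were S100P, a calcium-binding protein, which fell by 4.36 ± 0.28, SERPINF2 and SERPINF1, which fell by 3.57 ± 0.18 and 3.07 ± 0.27, DHRS7, which fell by 2.98 ± 0.22, ADA, adenosine deaminase, which fell by 2.89 ± 0.16, and MTMR9, which fell by 2.79 ± 0.20. The adjusted p of these 20 genes was at most 0.000158, and by the rule that chose them no array of a day overlapped the other day.

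With limma, 15553 of 31112 probes differed between days, 7396 higher and 8157 lower at day 24. Of these, 1677 were more than 2-fold higher and 1302 more than 2-fold lower. The called probes of named genes covered 2077 symbols with a higher and 2772 with a lower probe. Counts of list members called in 1 direction are to be read against the 7396 higher or the 8157 lower of 31112 probes. Counts of both directions together are to be read against the 49.99% called over all tested probes. Each day lay on its own slide, scanner and software version, so none of these differences can be told apart from a difference between slides. The count was 8798 with the line A channel alone against 13090 with the line R channel alone, 10158 among probes above background in both channels on all arrays, and 8840 without day 14 replicates 1 and 2.

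**Figure D3:**
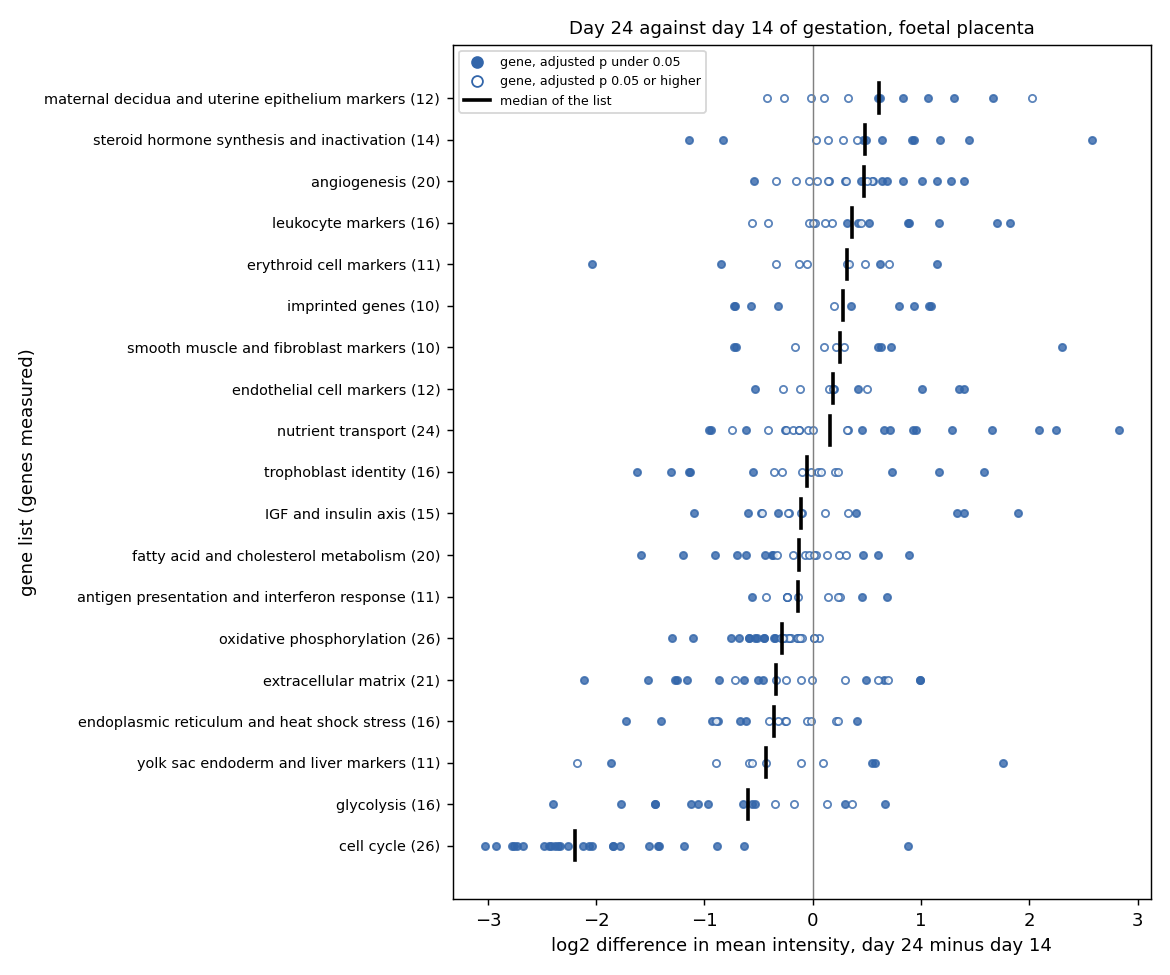
Log2 difference in mean intensity between day 24 and day 14 (horizontal axis) for each measured gene of the 19 lists (vertical axis), with filled points for called genes, open points for the others and a black bar at the list's median. The cell cycle list has its median at -2.19 and the maternal decidua and uterine epithelium markers at 0.61.

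Of 26 oxidative phosphorylation genes 13 fell, none rose and 13 did not pass, with a median of -0.29 (camera adjusted p = 0.00657, adjusted p = 0.531 with an estimated correlation). That median lay at percentile 7.29 of matched random lists, within their central 95%. The ATP synthase subunits ATP5F1A and ATP5F1C fell by 0.75 ± 0.09 and fell by 0.59 ± 0.10, and NDUFS3 of complex I fell by 0.52 ± 0.08. In glycolysis, 10 of 16 genes fell and 2 rose (median -0.60, camera adjusted p = 0.107). LDHA, lactate dehydrogenase A, fell by 1.77 ± 0.26, PGAM1 fell by 1.46 ± 0.27 and PGK1 fell by 0.97 ± 0.15. Of 20 genes of fatty acid and cholesterol metabolism, 8 fell and 3 rose (adjusted p = 0.528), among them IDI1 of the isoprenoid pathway, which fell by 1.58 ± 0.14, and ACADM, a fatty acid dehydrogenase, which rose by 0.89 ± 0.16. In the stress list, 6 of 16 genes fell and 1 rose (adjusted p = 0.0949), with the mitochondrial chaperonin HSPD1, which fell by 1.73 ± 0.12, and the chaperone HSPA5, which fell by 0.88 ± 0.15.

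Steroid genes rose as a group: 8 of 14 rose and 2 fell, with a median of 0.48 (camera adjusted p = 0.0271, adjusted p = 0.477 with an estimated correlation). STS, steroid sulfatase, rose by 1.44 ± 0.07, and SULT1E1, oestrogen sulfotransferase, rose by 2.58 ± 0.41, while CYP17A1, which makes androgens, fell by 0.83 ± 0.14. The members that rose thus included enzymes with opposite actions on steroid sulfates. From Agilent's processed signals the list had an adjusted p of 0.0556. SCARB1, the receptor that takes up cholesterol from HDL, rose by 1.17 ± 0.20. Angiogenesis genes also rose: 10 of 20 rose and 1 fell, 12 and 2 adjusted over the list alone, with a median of 0.47 (camera adjusted p = 0.00969, adjusted p = 0.396 with an estimated correlation). The endothelin receptor EDNRA rose by 1.15 ± 0.10, with its 3 probes between 0.09 and 1.15, the angiopoietin receptor TEK by 1.39 ± 0.21, and the receptors EPHB4 and FLT4 by 0.83 ± 0.11 and 1.28 ± 0.22. Of 24 nutrient transport genes 10 rose and 4 fell, 10 and 5 adjusted over the list alone (median 0.16, adjusted p = 0.187). The fatty acid translocase CD36 rose by 2.83 ± 0.12, lipoprotein lipase LPL by 2.09 ± 0.13, the transferrin receptor TFRC by 2.25 ± 0.19 and the fatty acid binding protein FABP3 by 1.66 ± 0.21.

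Trophoblast genes moved both ways, 3 of 16 rising and 5 falling, 4 and 5 adjusted over the list alone (median -0.06, camera adjusted p = 0.908). GCM1, a transcription factor of syncytiotrophoblast formation, rose by 1.17 ± 0.18, PPARG by 0.73 ± 0.08 and ITGA6 by 1.58 ± 0.12, with its 7 probes between 0.09 and 1.66, and TP63, a factor of epithelial progenitors, fell by 0.55 ± 0.09. In the IGF and insulin axis 4 of 15 rose and 4 fell (adjusted p = 0.908): IGF1R rose by 1.33 ± 0.15, the growth hormone receptor GHR by 1.89 ± 0.27 and IGFBP6 by 1.40 ± 0.20, and the RNA-binding protein IGF2BP1 fell (adjusted p = 0.00251). The probes of IGF1R were at 0.19 and 1.33. Of 10 imprinted genes 5 rose and 4 fell (adjusted p = 0.342), with PEG3 up by 1.07 ± 0.12 and NNAT, which fell by 0.72 ± 0.11. In the extracellular matrix list 9 of 21 fell and 4 rose (adjusted p = 0.462): BGN, biglycan, fell by 1.52 ± 0.17, VCAN, versican, fell by 1.26 ± 0.09, and LOX, lysyl oxidase, rose by 0.99 ± 0.09. Antigen presentation and interferon genes had 2 of 11 rising and 1 falling (adjusted p = 0.924).

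Markers of other cell types are given beside the 7396 probes called higher and 8157 called lower of 31112 tested, 49.99% for both directions together. Leukocyte markers rose, 8 of 16 with none falling (median 0.36, camera adjusted p = 0.0257, adjusted p = 0.477 with an estimated correlation), among them CD3D of the T cell receptor complex by 1.17 ± 0.10 and the B cell antigen MS4A1 by 0.88 ± 0.14. Maternal decidua and uterine epithelium markers rose, 6 of 12 with none falling (median 0.61, adjusted p = 0.0257, adjusted p = 0.396 with an estimated correlation), with PRL, prolactin, up by 1.66 ± 0.14, its other probe at 0.01, and the prolactin receptor PRLR by 0.83 ± 0.08. Of 12 endothelial markers 5 rose and 1 fell (adjusted p = 0.0969), with PECAM1 up by 1.35 ± 0.13. Of 10 smooth muscle and fibroblast markers 4 rose and 2 fell, 5 and 2 adjusted over the list alone (adjusted p = 0.187), with the smooth muscle myosin MYH11 up by 2.30 ± 0.20. Erythroid markers had 2 of 11 rising and 2 falling (adjusted p = 0.908), where ALAS2 of haem synthesis rose by 1.15 ± 0.23 and carbonic anhydrase CA2 fell by 2.04 ± 0.15. Of 11 yolk sac and liver markers 3 rose and 1 fell (median -0.43, adjusted p = 0.908). Camera's direction was upward against a median below 0 for this list and for the trophoblast, IGF and antigen presentation lists, none of them called. Counts not given adjusted over the list alone were the same there.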

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

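The tests of explanations and the splits for day 14 and for the mean of both days were chosen only after the results were seen, while the splits for day 24, for the change between days and for the comparison of days were chosen before. For 2 of these tests, of a lower share of 1 cell type and of a sequence variant, the limits were also rewritten after a first version had been run, and under the first limits the values would have argued against both explanations. Day 14 groups of 4 arrays were searched for an array far from the others, measured as its gap to the nearest array over the whole range; 6 of 84 groups met the limit, and chance gives about 1 in 20.

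The yolk sac endoderm and liver list had a ratio of 0.879, with a median log2 ratio of line A over line R of 2.20 on replicate 1 and -0.18, 0.10 and -0.05 on replicates 2, 3 and 4. The glycolysis list had a ratio of 0.837, with -0.51 on replicate 3 against 0.28, 0.26 and 0.15. That flag rests on the direction of replicate 3 as labelled, since turned, its median would have the sign of the others. POLI had a ratio of 0.868, with 0.80 on replicate 3 and -0.09 to 0.03 on the others. SAG had a ratio of 0.842 for a second probe, with -1.32 on replicate 1 and -0.82 to -0.72 on the others. With replicate 3 turned, SAG would stand above 0 on that array and below 0 on the others. SRD5A1 had a ratio of 0.914, with 0.72 on replicate 3 and 0.30 to 0.34 on the others. ACE had a ratio of 0.877 in mean log2 intensity, with 7.47 on replicate 4 and 8.54 to 8.69 on the others.

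The line difference itself differed between the stages for 2 lists by camera, the cell cycle list by a median of 0.36 and the oxidative phosphorylation list by a median of 0.19, and neither held with an estimated correlation.

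The line ratios of day 14 replicates 3 and 4 ran against each other across probes (r = -0.416). A dye effect as the whole cause is argued against by r = -0.130 between replicates 1 and 3, which share a dye orientation and would then correlate above 0. Different cell type make-up of the placentas paired on each array stays open. Of the 6 marker lists of other cell types, 1 lay outside the central 95% of matched random lists in opposite directions on replicates 3 and 4. This was the erythroid list, at 0.70 and -0.64. Reversed labels would give that too, and the imprinted genes, which are not cell type markers, lay at percentiles 99.51 and 0.96 on these arrays. Replicates 2 and 4 had erythroid medians of 0.97 and -0.64, yet r = 0.241 between them. This test thus cannot single out cell type make-up. Reversed dye labels on replicate 3 stay open. Of 8 probes with a ratio of at least 0.5 in 1 direction on the other 6 arrays, 5 (62.5%) kept that sign on replicate 3, too few to decide. By these labels, the authors' deposited columns had the same direction on all 4 day 14 arrays, replicate 3 included. They may rest on the same labels, so this does not decide. Turning replicate 3 raised the probes of 1 sign by at least 0.5 on all 4 day 14 arrays from 19 to 181. It raised those at an unadjusted p under 0.01 from 220 to 559, with 311 expected by chance. Both were the highest of the 8 assignments, but replicate 3 was turned because it disagreed, so these counts do not decide either. A difference between individual placentas of a line was not tested.

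The cell cycle list was lower at day 24 among the 15553 probes that differed between days. A slide or labelling effect that follows intensity or probe GC content is argued against, as the median of -2.19 lay at percentile 0 of 10000 matched random lists. A lower share of 1 cell type with all other types raised alike stays open: 8 of 16 leukocyte and 6 of 12 decidua markers rose (lists at adjusted p = 0.477 and 0.396 with an estimated correlation), while the yolk sac list had the lowest percentile of the marker lists, 1.64, with members going both ways. A slide or scanner effect of another kind and the stage itself cannot be told apart, because 0 slides held both days. Of 35 splits of the 7 arrays, 1, the real one, gave as many called probes, and the highest of the others gave 0. The other splits mix the days, so the difference between days widens their spread and few calls could come from them. The splits thus do not measure how often chance would give that number.

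For genes of smallest p between the lines, a sequence variant between the lines under single probes was weighed. Of 9 such genes with other probes on separate sequence, 5 (55.6%) had other probes with a difference over 0.5 times that of the named probe, which leaves the explanation open, and the median of that ratio, on which the first limit rested, was 0.650. For KCNE1 and SULF1 the other probes stood at -1.67 and -0.44, for TMED7, CEP350, FASTKD3 and RNASE4 at 0.07, -0.05, -0.15 and 0.36 against 0.74, -0.69, 0.54 and 0.75 for the named probe. A variant may bear on these last 4 genes and was not tested by sequence. The other 11 of the 20 genes could not be assessed. Of these, MDK, LACTB2, AARD, SLC45A1, PINLYP and SLC35B4 had 1 probe each. SAG, ITGAE, SLC7A9, NUDT15 and SLC6A4 had other probes only of shared sequence.

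For the number of called probes, other assignments of the lines to the dyes were compared with the real one. With 8 assignments at day 14 and 4 at day 24, no share under 0.05 can be had, and the real value and the highest other were 0 at both days. For the mean of both days and for the change of the line difference between days the real value was also 0, which every assignment or split reaches, so that count tests nothing; the highest others gave 13 and 5. By the number of probes at an unadjusted p under 0.01, used here after the results were seen, 20 of 62 assignments gave at least the real 426 for the mean of both days, the highest other 1125. For the change between days 10 of 34 splits gave at least the real 437, the highest other 765, and chance cannot be excluded for either of these numbers.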

How the results depend on the processing

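The settings with a turned day 14 replicate 3, without day 14 replicates 1 and 2 together and with a robust prior were chosen only after the results were seen. The number of probes called by limma between lines stayed at 0 at day 14 and for the change between days under every setting run, with 367 to 2430 and 740 to 2651 at an unadjusted p under 0.05. At day 24 it was 0, but 4 among the probes above background in both channels on all arrays, where fewer probes were tested, and for the mean of both days it was 0 to 1 with single arrays left out. For day 24 against day 14, 15553 became 10158 with that filter, 8798 with the line A channel only, 8840 without day 14 replicates 1 and 2, and 9794 with the replicate block, and 12851 to 15703 with single arrays left out; for the line A channel the cause was not tested. In the replicate block, the same-numbered arrays' intensity deviations correlated at -0.222, 0.0110 and -0.0371, so the numbers did not pair the arrays, and the block left 0 probes and gave 4 lists for the change between days against 2.

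Lists called with an estimated correlation were 0 in every comparison. At the preset correlation, with single arrays left out, the lists called were 3 to 5 at day 14 (3 with all arrays), 0 to 2 at day 24 (1), 1 to 3 for the mean of both days (3), 2 to 3 for the change between days (2) and 6 to 7 for day 24 against day 14 (6). With day 14 replicate 3 turned the lists called at the preset correlation were 6 at day 14 and 5 for the mean of both days, and without replicates 1 and 2 they were 1 and 1. At day 24 they were 2 with genes as the mean of their probes and 2 from Agilent's processed signals. The adjusted p of the yolk sac endoderm and liver markers at day 14 ran from 8.0733e-06 without replicate 2 to 0.878 without replicate 1, where the direction turned. APOA2 at day 14 ran from -0.063 without replicate 1 to 1.53 without replicate 3, and was -0.065 without replicates 1 and 2. The correlation of the line difference between days ran from -0.0625 without day 24 replicate 3, through -0.0547 without replicate 2, to 0.196 without replicate 1. It was 0.00956 to 0.117 with day 14 arrays left out and 0.125 with day 14 replicate 3 turned. Of probes at an unadjusted p under 0.01 at either day, where 0 were called, 382 of 694 had the same sign at both, and 562 of 971 with replicate 3 turned. The cause of these shifts was not tested beyond the arrays left out.

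Of 94 genes named for the comparison of days, 94 kept their direction in every setting run, 16 missed the threshold in at least 1 setting and 1 passed it only there. For the line comparisons, 31 of 32 genes kept their direction at day 14, 24 of 24 at day 24, 32 of 32 for the mean of both days and 18 of 18 for the change between days. These line genes were chosen by smallest p on the same arrays that the settings reuse, and none passed. Their kept direction is thus largely built in and is no evidence of a line difference. Genes at day 24 were not refitted with day 14 replicate 3 turned or without day 14 replicates 1 and 2. Of 200 values of named genes 57 moved by over 1.5 times from Agilent's processed signals, 56 of them away from 0, as did 16 of 82 with day 14 replicate 3 turned, 1 of them away from 0. Of the spots in a channel 50.8% to 80.4% were well above background, and among the 20171 probes above background in both channels on all arrays 0 were called by limma at day 14, for the mean of both days and for the change between days.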

Other observations

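The genes in this part were chosen after their values were seen, except where a list fixed in advance is named. ACE, the angiotensin-converting enzyme that rose with stage, had a higher ratio in line A on all 7 arrays as labelled, at 0.14, 2.03, 3.16 and 0.43 on day 14 replicates 1 to 4 and with a mean of 1.45 ± 0.72 (SD, n = 3) at day 24, but did not pass the test for the mean of both days (1.47, adjusted p = 0.700). With day 14 replicate 3 turned, its day 14 mean is -0.14. Probes A_04_P045422 and A_04_P005161, without a gene symbol here, were higher in line A by at least 0.5 on all 7 arrays as labelled, with means of 2.31 ± 1.40 and 1.20 ± 0.74 (SD, n = 7). Only 3 probes met that limit in either direction, and 5 of the 64 assignments of the lines to the dyes gave as many, the highest of them 9. At day 14 alone 19 probes did, against 181 with replicate 3 turned, and 4 of the 8 assignments gave as many. At day 24, 125 did, against 123 for the highest other assignment.

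Single arrays carried large ratios of cell type markers. On day 14 replicate 1, line A over line R was 5.32 for TTR, 3.89 for APOA2, 3.49 for AFP and 3.07 for APOB, all abundant products of yolk sac endoderm and foetal liver, and on replicates 2 to 4 TTR lay between -0.38 and -0.09. On day 14 replicate 2 it was 4.28 for S100A8, 3.16 for S100A9 and 2.45 for CD14, markers of myeloid cells, and 4.85 for beta globin HBB2 and 2.88 for alpha globin HBA. On day 24 replicate 3 the cell cycle list had a median of 0.66. Between 5 and 11 of the 19 lists lay outside the central 95% of matched random lists on each array, where 0.95 would be expected for lists of unrelated genes. Members of a real list can vary together, unlike those of random lists, so these counts do not measure a line difference.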
